A study of Mus musculus with 4 samples.

How the data were processed

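Chromatin from genital tubercles of wild-type CD1 mouse embryos at embryonic day 14.5 was studied by chromatin immunoprecipitation followed by sequencing (ChIP-seq), which maps where a protein is bound to DNA. Per the labels' protocols, tissue was fixed in 1% formaldehyde for 20 minutes, chromatin was sheared to 150 to 400 bp, and 500 µg of it was incubated with 5 µg of a rabbit monoclonal antibody against ISL1. Libraries were read as 75 bp single-end reads, per the labels' protocols. The series held 2 Isl1 ChIP samples and 2 input DNA samples (sheared chromatin without immunoprecipitation). Samples were grouped, and replicates numbered, by their titles. Each ChIP sample had 1 peak list. The input samples had no peak list and were not analysed here; any effect they had on the values came through the authors' peak calling, which the sources used here do not describe.

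Trimmomatic 0.35 (read trimming), Bowtie2 2.2.6 (alignment), MACS2 2.1.0.20150731 (peak calling) and bedtools are named in the submitters' processing notes, with build mm10. Those notes, as used here, give neither their order nor their settings, so the brackets state only what each tool is commonly used for. Each list held 1 line per peak with a position and a whole-number score that the authors deposited, and no summit, read count or strand. The formula behind the score, the threshold of the calls and the way the input was used are not given in the sources used here. The lowest score was 20 in both lists. Scores were used to rank and filter peaks within a list and, for shared regions, through the rank correlation between replicates and the lower of the 2 scores. Nothing in the sources states that scores are comparable between libraries, so a ranking by the lower score can weigh the replicates unequally. Read totals are not given in the lists, so the depth of each library is unknown and a difference in depth between the replicates could change how many weak peaks each list holds. A site whose signal lay under the authors' threshold does not appear, so a gene without a peak is not shown to be unbound.

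Peaks of the replicates were called shared where they overlapped by at least 1 bp. A shared region is the joined span of overlapping peaks that holds at least 1 peak of each replicate. Its midpoint, used for all distances, location classes and gene assignments, is that of the longest overlap between its peaks, not of the joined span. The overlap was set against 1000 placements in which each replicate 2 peak was moved by 20 to 500 kb either way on its own chromosome, which keeps the regional density of peaks. Scores of shared and unshared peaks were compared within each list by a two-sided permutation test of the medians with 100000 resamples. The correlation of scores between replicates was taken across regions, which are not independent replicates, with 10000 permutations. Shares carry Wilson 95% intervals and counts carry exact Poisson 95% intervals, and both cover counting error alone.

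Gene positions came from a RefSeq gene table of assembly GRCm38.p6, whose chromosome coordinates are those of mm10. It gives the start and end of each gene but neither strand nor exons, and no genome sequence was used. Distances to transcription start sites, which had been planned, were therefore replaced by distances to the nearest end of a protein-coding gene, whichever end that was, and promoter, UTR, exon and intron classes were replaced by 4 classes: within 1 kb of a gene end, inside a gene, outside genes within 100 kb, and farther. A region at a gene end can therefore lie at a promoter or at the other end of a gene. Planned searches for 28 fixed motifs and for all short sequence words were not run. Location was set against 1000 uniform placements of each region on its own chromosome between the first and last annotated gene or peak, with assembly gaps not excluded, and p-values were adjusted by Benjamini-Hochberg over the 4 classes or over the 6 distance measures. Alternatives for location used fewer placements, and there p-values of the median distance were not adjusted.

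A shared region inside a protein-coding gene was assigned to that gene, or to each gene it lay in, and any other region to the nearest gene within 100 kb. For 25 gene lists holding 555 distinct genes, all of them matched to the gene table, the number of genes with at least 1 assigned region was set against 10000 random lists of the same size. The random lists were drawn from the 21883 protein-coding genes in 20 bins of domain size, the stretch from which a gene receives regions, measured on a 1 kb grid. The p-values were two-sided, with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. The lists, 32 focus genes and the rules for naming further genes were fixed before the data were examined. Those rules took the 15 genes with most assigned regions, the 10 shared regions with the highest lower score of the 2 replicates, and 2 to 4 members of each list in the order of assigned regions. Some genes that these rules name are not reported here. The rule that a region inside a gene goes to that gene was set after the gene table had been seen and before any list was tested.

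The calculations were tested on simulated data. Of 500 random lists without an effect, 1 was called. There, regions were placed uniformly and list genes drawn at random, so the effect of crowded regions and of neighbouring list members on false calls was not covered. With 25 genes per list, 33 of 100 lists were called when 5 genes were given an added region and 100 of 100 when 10 genes were, so a list with a few bound genes can be missed. A planted overlap of 59.8% was recovered as 59.8%, and a planted share at gene ends of 22.0% as 22.2%. Alternatives covered the overlap rule, the placement of random regions, the stronger part of each list, the distance limit and the test for gene lists, regions away from gene ends, the gene set, and each replicate's list alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Nothing in the labels says that the replicates came from separate pools of embryos, so p-values describe these 2 samples, whose differences may be technical.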

Results

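The genital tubercle is the embryonic outgrowth that forms the penis or the clitoris, and Isl1 is a LIM-homeodomain transcription factor present in its mesenchyme. The series asked where Isl1 binds in tubercle chromatin at E14.5 (embryonic day), in 2 ChIP replicates, and its title ties Isl1 to signalling pathways of genital development. Replicate 1 had 8860 peaks with a median width of 172 bp (quartiles 130 and 249 bp), which covered 1.84 Mb. Replicate 2 had 10162 peaks with a median width of 185 bp (quartiles 136 and 270 bp), which covered 2.25 Mb. The authors' peak score had a median of 90 in replicate 1 (quartiles 59 and 156, maximum 1637) and of 96 in replicate 2 (quartiles 63 and 166, maximum 1638). All positions are in mm10.

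The first comparison asked how far the Isl1 sites of the replicates coincided. In replicate 1, 6952 of 8860 peaks (78.5%, Wilson 95% interval 77.6 to 79.3%) overlapped a replicate 2 peak. In replicate 2, 6936 of 10162 peaks (68.3%, 67.3 to 69.2%) overlapped a replicate 1 peak. Locally moved peaks overlapped in 27.8 cases on average for replicate 1, so the observed overlap was 250-fold higher (two-sided permutation p = 0.002, the smallest that 1000 placements can give). The overlapping peaks formed 6834 shared regions with a median width of 251 bp, of which 214 joined more than 1 peak of a list. The remaining 1908 peaks of replicate 1 and 3226 peaks of replicate 2 were in one list alone.

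Sharing followed the score. With each list divided into 10 score bins of like size, every peak in the highest bin of replicate 1 (886 of 886) and 1016 of 1017 in that of replicate 2 were shared, against 55.8% (52.5 to 59.0%) and 38.9% (36.0 to 42.0%) in the lowest bins. Shared peaks had a median score of 104 in replicate 1, against 60 for peaks of that list alone, and of 126 against 66 in replicate 2 (two-sided permutation p = 1e-05 in each, the smallest that 100000 resamples can give). Across the 6834 regions the scores of the replicates had a Spearman correlation of 0.717 (permutation p = 1e-04, the smallest that 10000 permutations can give). Regions are not independent replicates, and a score under the authors' threshold could not be seen in either list.

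**Figure D1:**
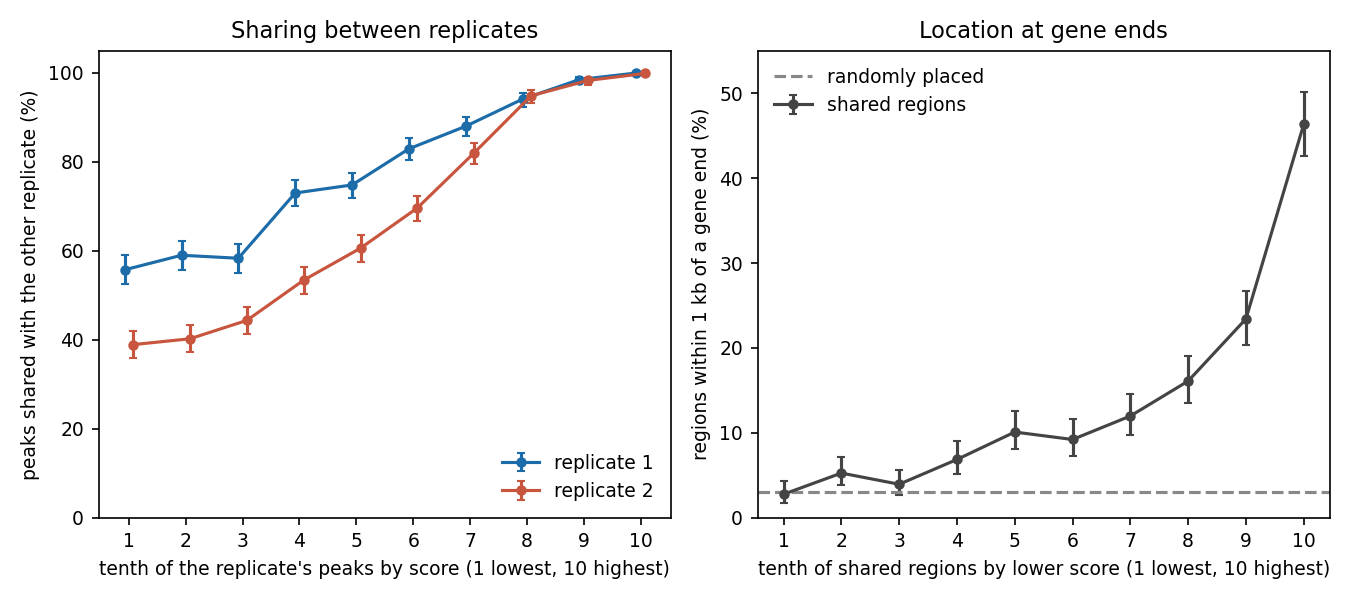
Left, percentage of each replicate's peaks that overlapped a peak of the other replicate, in 10 bins of the authors' score, with Wilson 95% intervals; the share was 55.8% and 38.9% in the lowest bins of replicates 1 and 2 and close to 100% in the highest. Right, percentage of shared regions within 1 kb of a protein-coding gene end, in 10 bins of the lower of the 2 scores, with Wilson 95% intervals and the value of randomly placed regions (3.0%, dashed); it was 2.8% in the lowest bin and 46.3% in the highest.

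The second comparison asked where in the genome the shared regions lay. Gene ends were the one class with more regions than random placement: 930 regions (13.6%, 12.8 to 14.4%) had their midpoint within 1 kb of a protein-coding gene end, against 3.0% of placed regions, a ratio of 4.54 (permutation test, adjusted p = 0.00266). The share was 13.2% over all replicate 1 peaks and 11.0% over all replicate 2 peaks. A further 2520 regions (36.9%) lay inside genes, against 38.3% (adjusted permutation p = 0.02), 1617 (23.7%) outside genes within 100 kb, against 30.1% (adjusted permutation p = 0.00266), and 1767 (25.9%) beyond 100 kb, against 28.6% (adjusted permutation p = 0.00266). The median distance to a gene end was 52.6 kb against 50.6 kb for placed regions (permutation test, adjusted p = 0.232). The share inside genes did not pass in either replicate's list alone, and against local moves the share beyond 100 kb was slightly above its expectation, 25.9% against 25.3% (adjusted permutation p = 0.126), while the median distance exceeded the 48.0 kb of the moved regions (adjusted permutation p = 0.00664). In replicate 2 alone it was 55.6 kb against 51.0 kb placed (adjusted permutation p = 0.00664). In the stronger part of the regions the median distance was lower, 38.7 kb against 50.1 kb (adjusted permutation p = 0.00664).

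Location at gene ends rose with the score, from 2.8% (1.8 to 4.3%) of regions in the lowest of 10 score bins to 46.3% (42.6 to 50.1%) in the highest. Of the 10 regions with the highest lower score, 6 lay within 1 kb and 8 within 5 kb of a gene end. The strongest was on chromosome 3 from 108209866 to 108210313, 291 bp from an end of Atxn7l2, with scores of 1568 and 1556 in replicates 1 and 2. The next lay inside Rpl22, a ribosomal protein gene (chromosome 4, 152325481 to 152325874, scores 1510 and 1638). Regions within 1 kb of an end of Proser1, Cenpu (a centromere protein), Zfp668, Tardbp (the RNA-binding protein TDP-43) and Rnf44 followed, together with regions inside Baz2a and Arid1a, which encode chromatin remodelling subunits. The remaining region of the 10 was 48.8 kb from its nearest gene, E330021D16Rik, on chromosome 6 (136468482 to 136468867, scores 1637 and 1244). No gene of the signalling, tubercle or matrix lists was nearest to any of these 10.

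The third comparison asked whether regions lay at genes known in genital tubercle development. Of the 32 focus genes, 22 had at least 1 assigned shared region, and their neighbourhoods were crowded: the median number of regions within 500 kb was 6, against 2 over all protein-coding genes (described, not tested). Isl1 itself had 5 assigned regions, where its domain size alone gave 0.561, and 13 lay within 500 kb. None was inside the gene (chromosome 13, 116298270 to 116309688). The closest was 3.62 kb away (116313188 to 116313370, scores 22 and 33), and stronger ones flanked it on both sides, with peaks at 116278797 to 116279175 in replicate 1 (score 302; 371 for the replicate 2 peak) and at 116318203 to 116318688 (score 327; 256 in replicate 2).

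Bmp4, which encodes a bone morphogenetic protein, had 3 assigned regions and 12 within 500 kb, none inside the gene (chromosome 14, 46383525 to 46390669), and the closest was 19.6 kb away (46363786 to 46364000, scores 36 and 82). Replicate 1 alone placed 5 peaks there. Fgf10, a mesenchymal fibroblast growth factor, had 2 regions, of which 1 lay inside the gene (chromosome 13, 118731838 to 118732150, scores 196 and 184). With at least 50% reciprocal overlap required, 1 of the 2 was left. Wnt5a, a Wnt ligand of outgrowing appendages, had 1 assigned region, 31.1 kb away on chromosome 14 (28558459 to 28558725, scores 302 and 130), and 2 in replicate 1 alone. Within 1 Mb of Wnt5a lay 31 regions, many of them inside its large neighbours Erc2 and Cacna2d3 and hence assigned to those.

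**Figure D2:**
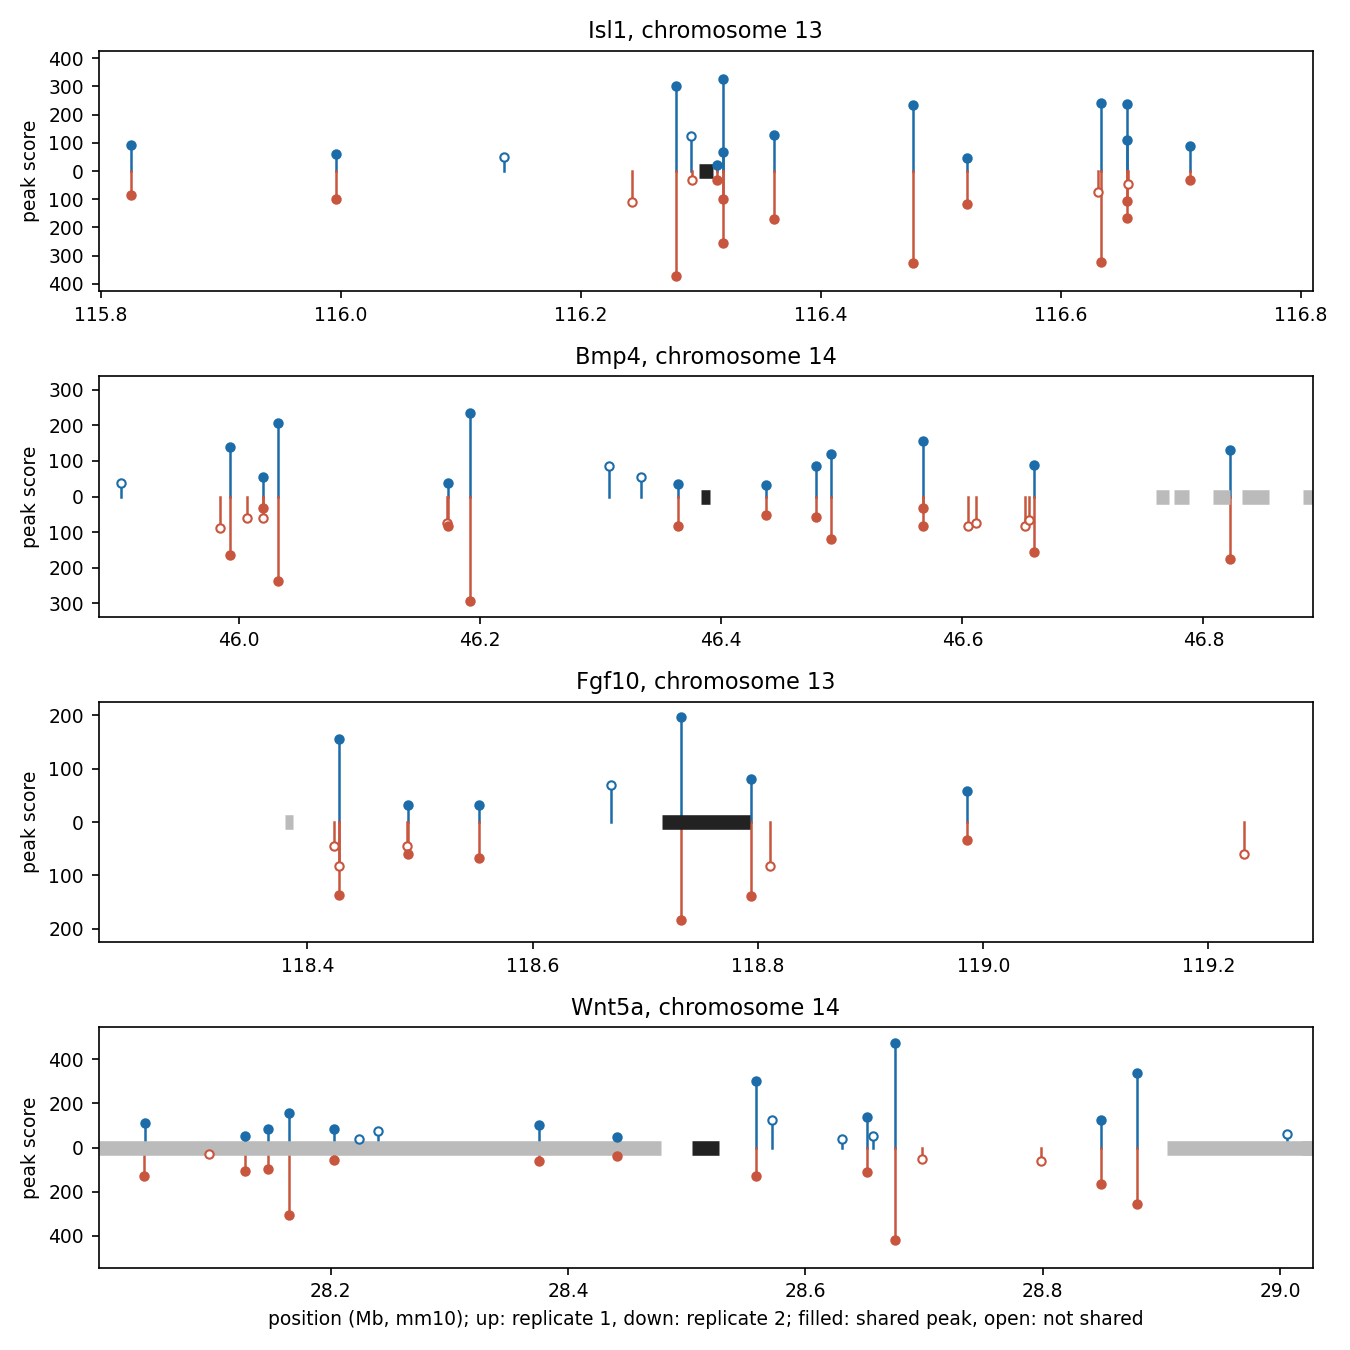
Peaks within 500 kb of Isl1, Bmp4, Fgf10 and Wnt5a along the mm10 position in Mb, with the authors' score of each peak as height, replicate 1 upwards and replicate 2 downwards. Filled points are shared peaks and open points are not shared, black bars are the named gene and grey bars other protein-coding genes; 13, 12, 6 and 12 shared regions lay in the 4 windows, most of them outside the named gene.

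Among hedgehog genes, Shh, the ligand made by the urethral plate, had no shared region within 500 kb, and its nearest was 665 kb away, although replicate 1 alone assigned 1 peak to it. Its receptor Ptch1 had 2 regions, both inside the gene, with scores of 327 and 171 for the one at chromosome 13, 63563092 to 63563399, and 18 within 500 kb. That window takes in most of Aopep, a neighbouring gene with 11 assigned regions of its own. Each replicate alone gave Ptch1 more peaks, 5 in replicate 1 and 4 in replicate 2. The hedgehog effector Gli1 had 2 regions, one inside the gene with scores of 622 and 583, Gli3 had 1 and Hhip had none. Among Wnt genes, the feedback inhibitor Axin2 had 3 regions, with scores of 338 and 253 for one inside it (chromosome 11, 108920171 to 108920956). Dkk2, a secreted Wnt antagonist, had 3 and the nuclear effector Lef1 had 2, whereas Ctnnb1, the gene of beta-catenin, had none within 500 kb. Bmp7, the homeobox gene Msx1 and Tbx4 each had 3, Spry2 had 2, and Bmp2, Msx2, Fgfr2 and Tbx5 had 1. Of the retinoic acid genes, the receptor Rarb had 3 regions inside it, and the synthetic and degrading enzymes Aldh1a2 and Cyp26b1 had 1 each. Nog, Fgf8, Hoxa13, Hoxd13 and Pitx1 were among the other focus genes with none assigned, although 16 regions lay within 500 kb of Hoxd13 and 7 within 500 kb of Hoxa13. A region with scores of 977 and 990 lay 40.7 kb from Fgf8 and was not assigned to it. Domain size alone gave 0.125 for Fgf8, 0.0903 for Hoxa13, 0.0239 for Hoxd13, 0.298 for Pitx1 and 0.388 for Nog. A count of 0 therefore says little at these genes. Replicate 1 alone assigned 1 peak to Hoxd13. Single lists also gave more peaks than there were shared regions at Dkk2 (5) and Msx2 (4) in replicate 2, at Bmp7 (5), Tbx4 (5) and Rarb (8) in replicate 1, and at Bmp2, Aldh1a2, Fgfr2 and Tbx5 (2 in one or both lists). Tbx5 had none with reciprocal overlap and Rarb none by the nearest gene end.

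The fourth comparison asked which gene groups held more Isl1 regions than genes of like domain size. In total 5067 regions (74.1%) were assigned, to 3086 of 21883 protein-coding genes (14.1%). Of the 25 lists, 3 passed: transcription factors of the tubercle, mesenchyme and extracellular matrix genes, and the Wnt pathway (random matched lists, permutation test, adjusted p = 0.00167 in each). Transcription factors of the tubercle had a region at 19 of 31 genes, against 6.28 in matched lists (95% range 2 to 11). Isl1 and Twist2 had 5 regions each and Alx4 had 4. Mesenchyme and matrix genes had one at 17 of 23, against 5.77 (2 to 10), with 5 regions at Col1a2, a chain of type I collagen, and 3 each at Col5a2, Fbn2 and Postn (Col5a2 and Fbn2 had 5 peaks each in replicate 2 alone). Wnt pathway genes had one at 22 of 41, against 9.40 (5 to 14), with 5 regions at the Wnt inhibitor Apcdd1 and 3 each at Axin2, Dkk2 and the receptor gene Fzd2. With regions limited to 10 kb from a gene, the tubercle transcription factors had 7 genes against 2.45 and no longer passed (adjusted permutation p = 0.0875). With reciprocal overlap, Twist2 and Apcdd1 had 3 regions each in place of 5.

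**Figure D3:**
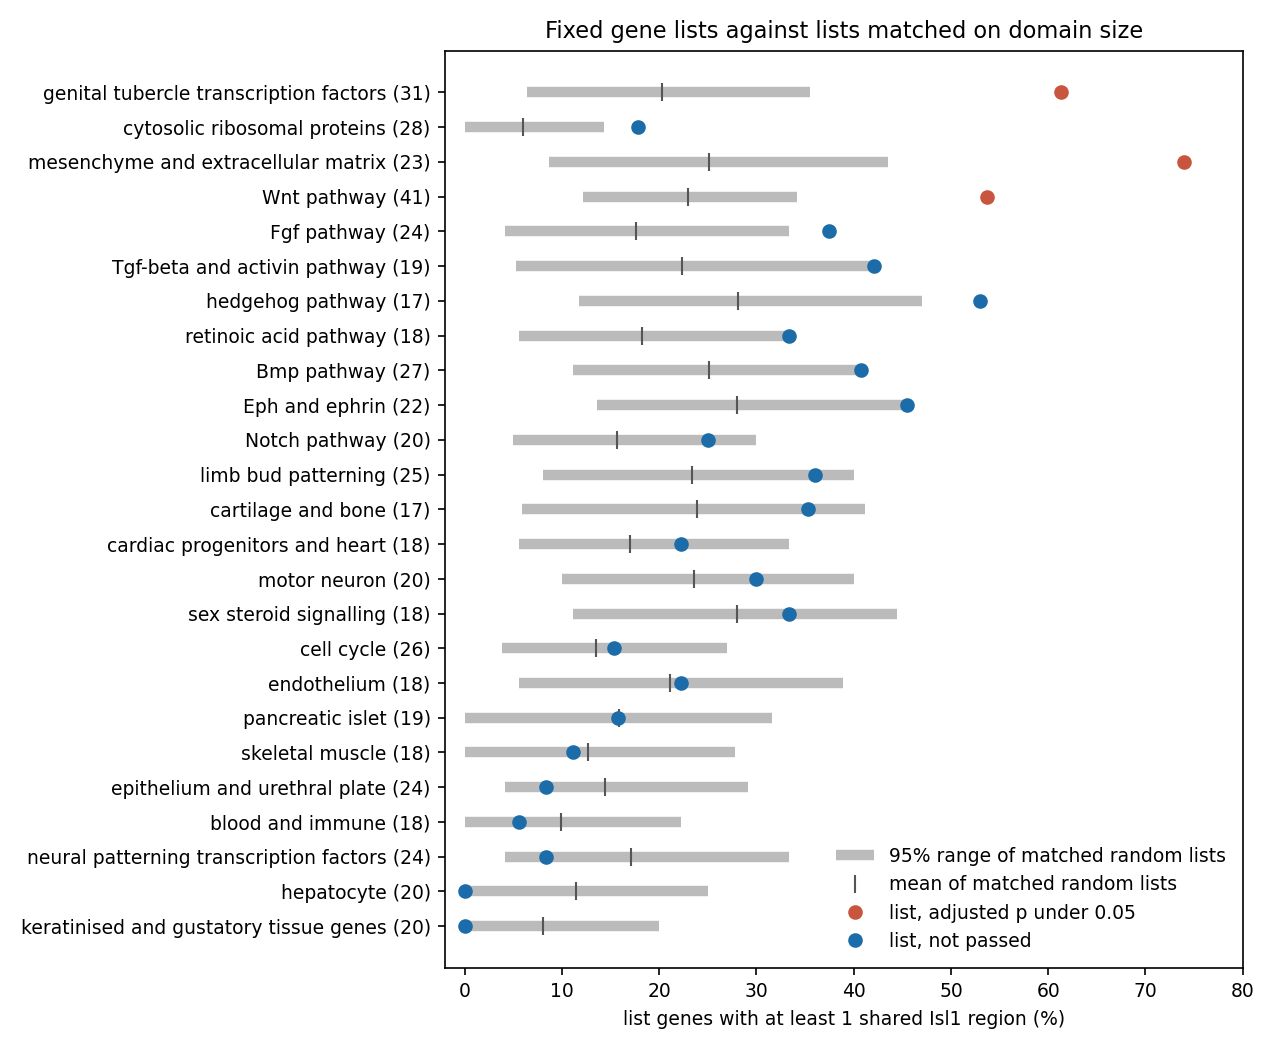
Percentage of the genes of each list that had at least 1 assigned shared region (points, number of genes in brackets), with the mean (tick) and 95% range (grey bar) of 10000 random lists matched on domain size, ordered by the ratio of the 2. The 3 lists in red passed at an adjusted p of 0.00167; hepatocyte genes and keratinised and gustatory tissue genes had no assigned region.

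The other signalling lists lay above their matched means without passing. Hedgehog genes had a region at 9 of 17 against 4.77 (adjusted permutation p = 0.138), where Boc and Gli2 had 3 each. Replicate 2 alone gave Boc and Gli2 5 peaks each and Ptch1 4, and replicate 1 alone gave them 4, 4 and 5. Fgf genes had one at 9 of 24 against 4.24 (adjusted permutation p = 0.138), with 5 regions at Fgf9. Bmp genes had one at 11 of 27 against 6.78 (adjusted permutation p = 0.252), with 5 at the inhibitory Smad6 and 3 each at Bmp5 and Bambi. Tgf-beta and activin genes had one at 8 of 19 against 4.24 (Ltbp1 4, Smad2 3) and Eph and ephrin genes at 10 of 22 against 6.17 (Efna5 4, Epha4 3), both with an adjusted permutation p of 0.211. In replicate 2 alone Ltbp1 had 8 peaks, Efna5 7 and Epha4 6. Retinoic acid genes had one at 6 of 18 against 3.28 (Rara and Rarb 3 each, adjusted permutation p = 0.347), and Notch genes at 5 of 20 against 3.13 (Hes1 and Rbpj 2 each, adjusted permutation p = 0.585). Hedgehog genes passed with a limit of 1 Mb, Bmp genes in replicate 2 alone (16 genes against 8.42), Fgf genes by the number of regions (19 against 6.40), and these 3 lists and the Tgf-beta list in a binomial test by domain size, which does not match genes.

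None of the lists for other cell types, for organs in which Isl1 acts or for general cell functions passed. Limb bud patterning genes had a region at 9 of 25 against 5.84 (adjusted permutation p = 0.364), with 5 at Meis1. Motor neuron genes had one at 6 of 20 against 4.71, with 5 regions inside the axon guidance gene Slit2 and 4 each in Gfra1 and Slit3. Cardiac genes had one at 4 of 18 against 3.06 (Smarcd3 3, Mef2c 2), pancreatic islet genes at 3 of 19 against 3.01 (among them Pcsk1 and Sst with 1 each), and sex steroid genes at 6 of 18 against 5.03 (among them Esr1 and Srd5a2 with 3 each). Cartilage and bone genes had one at 6 of 17 against 4.05 (Sox6 3, Col11a1 2), endothelial genes at 4 of 18 against 3.80 (Erg 2, Cdh5 1) and cell cycle genes at 4 of 26 against 3.50 (Cdkn1b 3, Cdk1 2). Epithelial and urethral plate genes had one at 2 of 24 against 3.46 (Krt8 and Grhl3), skeletal muscle genes at 2 of 18 against 2.29 (Pax3 and Ttn), blood and immune genes at 1 of 18 against 1.78 (Ptprc) and neural patterning transcription factors at 2 of 24 against 4.10 (Emx2 and Sox2). Hepatocyte genes (0 of 20 against 2.28) and keratinised and gustatory tissue genes (0 of 20 against 1.61) had none. In replicate 2 alone, 1 hepatocyte gene (against 2.87) and 2 keratinised and gustatory tissue genes (against 1.99) had a peak. Of the ribosomal protein genes on the list, which leaves out Rpl22, 5 of 28 had a region against 1.68 (Rpl3, Rpl5, Rpl7, Rpl19 and Rpl32 1 each, adjusted permutation p = 0.183). This list passed with a limit of 1 Mb, as did the limb bud list. In replicate 2 alone, 4 skeletal muscle genes had a peak (against 2.82), and in replicate 1 alone, 2 blood and immune genes did (against 2.17). Counts at several of these genes moved by over 1.5 times with the list or rule used. In replicate 2 alone Col11a1 had 5 peaks, Pax3 and Erg 4 and Sst 2, and in replicate 1 alone Srd5a2 had 5 and Krt8 and Sst 2. With reciprocal overlap Pax3, Ttn, Cdh5 and Sst had none, and by the nearest gene end Smarcd3 had none, Esr1 and Erg 1 and Slit3 2. Adjusted p-values of the lists given here without one lay between 0.347 and 1.

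The genes with most assigned regions were mostly long genes with the regions inside them. Dnm3, a dynamin gene, had 20 regions, all inside it, where its domain size gave 1.39 (Poisson 95% interval of the count 12.2 to 30.9). All genes of this paragraph were picked for their high counts, and neither the interval nor the values by domain size allow for that choice. The axon guidance receptor genes Robo2 and Robo1 had 19 (4.52 by domain size) and 15 (3.24), the methyltransferase gene Smyd3 had 16 (1.54), and Rad51b, a DNA repair gene, had 15 (1.73). Adk, Erc2 and Cacna2d3 had 14 each and Vps13b had 13. Aopep, Adamtsl1, Macrod2 and Arhgap15 had 11 each, and Arid5b and Kcnma1 had 10. These counts depend on giving a region inside a gene to that gene: by the nearest gene end within 100 kb, Dnm3 had 9 regions, Smyd3 6, Robo1 3, Robo2 2, Erc2 1 and Macrod2 none, while Arid5b had 10 and Aopep 9. In replicate 2 alone Rad51b, Macrod2, Adamtsl1, Aopep and Arhgap15 had more than 1.5 times as many peaks as shared regions (24, 19, 17, 17 and 17).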

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

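The nearest gene end, the finer bins of domain size and the local moves for location were chosen after the data were seen, and the other alternatives before. Of 736 results under alternatives, 629 kept their direction and their side of the threshold or stayed within the limits set for a value, 3 lost a call, 11 gained one, 68 moved (66 of them counts of regions at single genes) and 25 changed direction, of which 22 were gene lists that passed in neither case. The overlap of the replicates stayed at 68.6% or more for replicate 1 and 59.8% or more for replicate 2, the correlation between replicates at 0.667 or more (the value for widths in place of scores), and the share at gene ends at 11.0% or more, always above placement. Wnt genes and mesenchyme and matrix genes passed in 12 of 12 settings and tubercle transcription factors in 11 of 12. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, had no peak list. Motif and sequence word searches, exon and UTR classes and the start sites of every transcript were not run, because no strand, exon or genome sequence was used. Unknown read depth limits what an unshared or missing peak can show.

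The share inside genes was 33.5% against 33.3% placed once gene ends reached to 5 kb, which narrows the class, and 37.4 to 37.8% in the list of either replicate alone (adjusted permutation p = 0.093 and 0.319). The median distance to a gene end was 38.7 kb in the stronger part of the regions. In either replicate's list alone it was 52.1 to 55.6 kb, passing in replicate 2 (55.6 against 51.0 kb placed, unadjusted permutation p = 0.00664). Under local moves it was 52.6 kb, above its expectation, and the share beyond 100 kb (25.9%) also exceeded its expectation. Within 10 kb, tubercle transcription factors had 7 genes with a region, the call lost, and endothelial genes 1. Within 1 Mb, 6 lists passed, with hedgehog genes at 10, and endothelial genes at 4 fell under their mean. Fgf genes passed by the number of regions (19), where endothelial genes (5) and blood genes (3) changed direction. By the binomial test 7 lists passed, with hedgehog at 16 regions, Bmp at 27, Fgf at 19 and Tgf-beta at 16, and cartilage (9), endothelial (5) and blood (3) genes changed direction. In the stronger part of the regions sex steroid (3), endothelial (1) and motor neuron (2) genes, away from gene ends skeletal muscle (2), blood (1), ribosomal (0) and cell cycle (2) genes, and under reciprocal overlap endothelial genes (3) changed direction. In either replicate's list alone Bmp genes ranged from 12 to 16, passing in replicate 2. Skeletal muscle genes (3 to 4) changed direction in both lists, keratinised and gustatory genes (1 to 2) in replicate 2 alone, and endothelial (4 to 5) and cell cycle (4 to 5) genes in replicate 1 alone. Skeletal muscle genes (2) changed direction also by the nearest gene end and with 100 bins. Of these shifts, the narrower gene class apart, the cause was not tested.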

Other observations

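All tests in this part were chosen after the results they concern had been seen, apart from the comparison of X genes with matched autosomal genes and the removal of neighbouring list members, which were written down before their results. Of the 20 stretches of 500 kb richest in shared regions, the first overlapped Dnm3 alone (20 regions), the second Vps13b, Cox6c and Rgs22 (19) and the third Adk and Kat6b (17). Others held Creb5 (16), Arid5b (15), Dcn and Lum (14) and Tbx2 and Tbx4 (13). Of the 20, 3 overlapped no protein-coding gene: one on chromosome 18 (55287842 to 55787841) with 14 regions, one on chromosome 5 (118778359 to 119278358) with 14 and Tbx3 within 500 kb, and one on chromosome 3 (39265276 to 39765275) with 13. Genes of the Wnt, tubercle transcription factor or matrix lists within 500 kb of such stretches were Osr2, Prrx1, Dcn, Lum, Tbx2, Tbx3, Tbx4 and Lox (described, not tested). Most of the 20 stretches had no such gene within 500 kb, among them those of Dnm3, of Adk and Kat6b, of Creb5 and of Arid5b. The share for stretches chosen at random was not computed. Of the 31 tubercle transcription factors, 1, Hoxa10, had a shared region within 1 kb of a gene end.

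The crowding of regions reached beyond the genes' own domains, which extend no farther than the distance limit for assignment. Regions past that limit were counted even where the listed gene was still the nearest. Isl1, for example, had 5 assigned regions and 13 within 500 kb, a window with no other protein-coding gene. How much of the crowding lay in the domains of other genes was not tested. Without the regions assigned to the gene itself, tubercle transcription factors had 254 regions within 500 kb, summed over genes, against 75.6 in lists matched on gene density, matrix genes 137 against 57.1, and limb bud genes 119 against 59.1 (adjusted permutation p = 0.00333 in each of these 3). Wnt genes had 172 against 106 (adjusted permutation p = 0.00625). Of the 25 lists, these 4 passed. Listed ribosomal protein genes had 104 against 70.0 and Bmp genes 106 against 68.7 (adjusted permutation p = 0.0592 in both). Cardiac genes (26 against 39.8) and pancreatic islet genes (29 against 47.0) lay below their matched lists without passing. Crowding at the level of Wnt genes was therefore not shown to be particular to tubercle pathways. Counting a stretch more than once for neighbouring members was argued against, since with 1 member per 1 Mb the largest adjusted p of the tubercle, matrix and Wnt lists was 0.0187. No biological explanation could be tested, since the series has a single tissue, age and genotype.

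The strongest regions lay at gene ends, and 2 technical explanations were tested. Signal at any open promoter of a widely expressed gene stays open. Of the ribosomal protein genes on the list, 4 of 28 (14.3%, Wilson 95% interval 5.7 to 31.5%) had a shared region within 1 kb of an end. This was a minority, yet above the 4.89% of all protein-coding genes. The list does not hold every ribosomal protein gene. Rpl22, which holds a region among the 10 strongest, 1.28 kb from a gene end, is not on it. The share ran from 0 of 20 hepatocyte genes to 4 of 22 Eph and ephrin genes over the lists, so a raised share was not particular to ribosomal genes. A place in gene-dense stretches was argued against by local moves, which left 4.92% on average and 8.04% at most of the highest of 10 score bins at gene ends, where 46.3% had been seen. Binding of the antibody to other proteins at promoters stays open, since neither embryos without Isl1 nor another antibody were among the samples analysed here. No biological explanation was tested.

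Chromosome X held 107 shared regions, 0.626 per Mb against 2.75 per Mb on the autosomes, a ratio of 0.227 (Poisson 95% interval 0.186 to 0.275), and the ratio was 0.221 and 0.213 over all peaks of replicates 1 and 2. A smaller number of genes on X was argued against, since 66 of 966 X genes had a region where autosomal genes of the same domain size gave 191 (170 to 213, permutation p = 0.0002). Genes of like domain size span like stretches of DNA, so this partly repeats the lower density. The kind of genes on X was not matched and stays open. The deficit held among the highest-scoring regions, taken by 1 score cut over the whole genome: 28 on X and 1636 on autosomes, a ratio of 0.245 (0.163 to 0.353). With a lower cut it was 0.253 (59 regions on X), and with a higher one 0.148 (7 regions on X). This does not decide whether regions on X were lost under the threshold, since lower scores throughout X would take regions under any such cut. Fewer copies of X in male embryos could lower the scores there, but the median score was higher by 18 on X (109 against 91, bootstrap interval -6 to 46), which decides nothing because only peaks over the threshold are seen, and the sex of the embryos is not in the labels. Repeats and mapping on X stay open, since no genome sequence was used.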
